A study of Mus musculus with 2 samples.

How the data were processed

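Total RNA from mouse T cells was hybridised as biotin-labelled target to single-colour Affymetrix 3' expression arrays carrying 45101 probe sets. The cells were peripherally induced regulatory T cells that had been raised in vivo through dendritic cells and purified by flow cytometry on CD25 and Foxp3, per the labels. There were 2 arrays, 1 of Hopx-sufficient and 1 of Hopx-deficient cells, and each array took its group from its sample title. RNA was isolated with Trizol and cleaned up with QIAGEN reagents, per the labels' protocols. How many mice or sorts went into each array is not given in the sources used here, and neither are the scanner software, the summarisation method and the normalization between arrays.

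The authors deposited log2-type values that had been centred for each probe set on the mean of the 2 arrays. This was tested on the table: the columns are mirror images, the largest absolute sum of a row being 1e-06, and they run from -2.71 to 2.71. The median was -0.0076 in the Hopx-sufficient column and 0.0076 in the Hopx-deficient column. The deposited values therefore keep the difference between the arrays and no signal level, so the signal of a probe set, and whether it was detected, cannot be given. The log base is not stated. The steps between the single-precision values place the uncentred values between 2 and 16, which rules out log10 but not natural logs. For single probe sets the steps give at most a coarse bound on the signal, which was used only to leave out those with the finest steps. Base 2, the usual base for these arrays, was assumed. Had natural logs been used, every log2 difference printed here would be larger by a factor of 1.44. Direction follows from the column labels, and Hopx itself was lower in the Hopx-deficient column. The number of arrays limits the precision: with 1 array per genotype no difference has a replicate error, no test across genes was made and no p-value is given.

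Probe sets were named through the platform annotation of 2016, and symbols were updated by gene ID through a mouse gene table (GRCm38.p6), in which the IDs of 34741 of the 34945 probe sets with 1 symbol were found. A further 932 probe sets with several symbols, 9160 with none and 64 control probe sets were kept out of gene counts. The difference was taken as Hopx-deficient minus Hopx-sufficient and centred on its median over the probe sets with 1 symbol (0.0075 before centring). The value of a gene was the mean over its probe sets, which gave 18193 genes, 9183 of them with 1 probe set. A threshold of 2-fold was set as a rule of size and not as a test. For each gene list the median difference was placed among the medians of 10000 random gene lists of the same size, matched on the number of probe sets per gene, and a list was said to stand apart when its median lay outside the central 95% of the random medians. That place describes these 2 arrays and is not a p-value. For a simulation, differences were shuffled over the 34945 probe sets with 1 symbol, and list members were drawn at random from the 18193 genes. Each setting had 50 simulated lists, placed among fewer random lists than the 10000 used for the data, so the percentages are coarse. Of lists of 25 genes with no shift 2% were placed as higher, against 62% with a shift of 0.1 and 100% with a shift of 0.2. Lists of 10 genes were placed as higher in 2%, 30% and 92% of simulations, in the same order. Members drawn this way do not vary together, so the simulation does not show how often a list of co-regulated genes would stand apart. Python 3.11.15, numpy 2.4.6 and pandas 2.3.3 were used.

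Thresholds, 24 gene lists and the rule for named genes were fixed before the data were examined; 6 further lists were added after (ribosome biogenesis, supply of building blocks, FOXO-linked genes, antigen processing for MHC class I, oxidative phosphorylation and tissue macrophage markers). The genes named are Hopx, the 15 genes at each end of the ranking, the 3 members of each list that differed most, every member at least 2-fold apart in the AP-1, immediate-early, regulatory T cell and cytokine lists, and Foxp3 and Il2ra, whose products were used in the sort; other genes named were chosen after their values were seen. Since the table holds no levels, some of the planned steps could not be made as written: a filter at the median signal, the choice of the brightest probe set of a gene and the matching of random lists on signal were replaced by no filter, the mean over probe sets and matching on the number of probe sets. The spread was described over all genes and not by signal level. The alternatives were no centring, thresholds of 1.5-fold and 3-fold, the median or the most different probe set of a gene, removal of probe sets that can cross-hybridise by their suffix, removal of probe sets with the finest value steps, natural logs, random lists matched on size alone, and lists without shared members.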

Results

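The data compared gene expression in regulatory T cells (Tregs) that had formed in vivo through dendritic cells (DCs) in the presence or absence of Hopx, after immunization. Hopx is a small homeodomain-only transcription cofactor that does not bind DNA itself. Cells carrying both CD25 and Foxp3 were sorted, and 1 array was hybridised for Hopx-sufficient cells and 1 for Hopx-deficient cells. All values below are log2 differences, Hopx-deficient minus Hopx-sufficient, or the folds that correspond to them. No difference has a replicate error, so spread is given only between probe sets of the same gene, and a value describes these 2 arrays.

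The Hopx transcript itself was 35.6-fold lower on the Hopx-deficient array, the largest difference of any gene. Both of its probe sets showed this, with log2 differences of -4.87 (29.3-fold) and -5.44 (43.3-fold), as the labels require. Which part of the gene was deleted is not given in the sources used here. Of the other protein-coding genes next to Hopx on chromosome 5, 10 on each side, 18 were measured, and their median difference was -0.02, with a range from -0.54 (Ppat) to 0.28 (Nmu). Foxp3, the Treg lineage factor, differed by 0.28 (1 probe set). Il2ra, which encodes CD25, differed by -0.06, with probe sets at -0.19 and 0.08. Both proteins were used in the sort, so their levels are no independent result.

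Across 18193 genes, 26 were at least 2-fold lower and 2 were at least 2-fold higher in Hopx-deficient cells. At 1.5-fold the counts were 238 lower and 54 higher, and 98.4% of genes lay within 1.5-fold. The standard deviation of all gene differences was 0.21, and the central 95% ran from -0.48 to 0.38. Probe sets of the same gene gave the available check on single values. In the 9010 genes with 2 or more probe sets, the standard deviation within a gene was 0.18, and the differences of 2 probe sets of a gene correlated across genes with r = 0.42 (0.39 without Hopx), where genes are not independent replicates. Where 1 probe set of a gene, drawn at random, was at least 1.5-fold apart (173 genes), a second one lay on the same side in 89.0% of genes, against 59.9% over all genes, and 47 of the 173 were at least 1.5-fold apart by both.

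After Hopx, the most reduced genes were Hacd1, a dehydratase of very-long-chain fatty acid synthesis (5.44-fold lower, probe sets at -2.20 and -2.69), and Gzmb, the cytotoxic protease granzyme B (4.48-fold lower, 1 probe set). Gzma, which encodes granzyme A, was 2.34-fold lower. Interferon-induced genes filled much of the rest of this end, with Ifit1 at 3.23-fold, Oasl2 at 3.08-fold, Ifit3 at 2.91-fold, Mx1 at 2.88-fold, Oas3 at 2.32-fold and the chemokine gene Cxcl10 at 2.33-fold lower. Hspa1b, an inducible Hsp70 gene, was 2.60-fold lower, with its 3 probe sets between -1.40 and -1.34. It is nearly identical to Hspa1a, whose 1 probe set differed by -0.53, and the arrays may not separate the 2 genes. Also among the 15 lowest were the organic anion transporter gene Slco4a1 (2.45-fold lower), the spermidine synthase gene Srm (2.36-fold), Gm9706 (2.34-fold) and the Hedgehog signal transducer Smo (2.35-fold). The probe sets of Smo disagreed in size, at -2.19, -1.46 and -0.04.

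**Figure D1:**
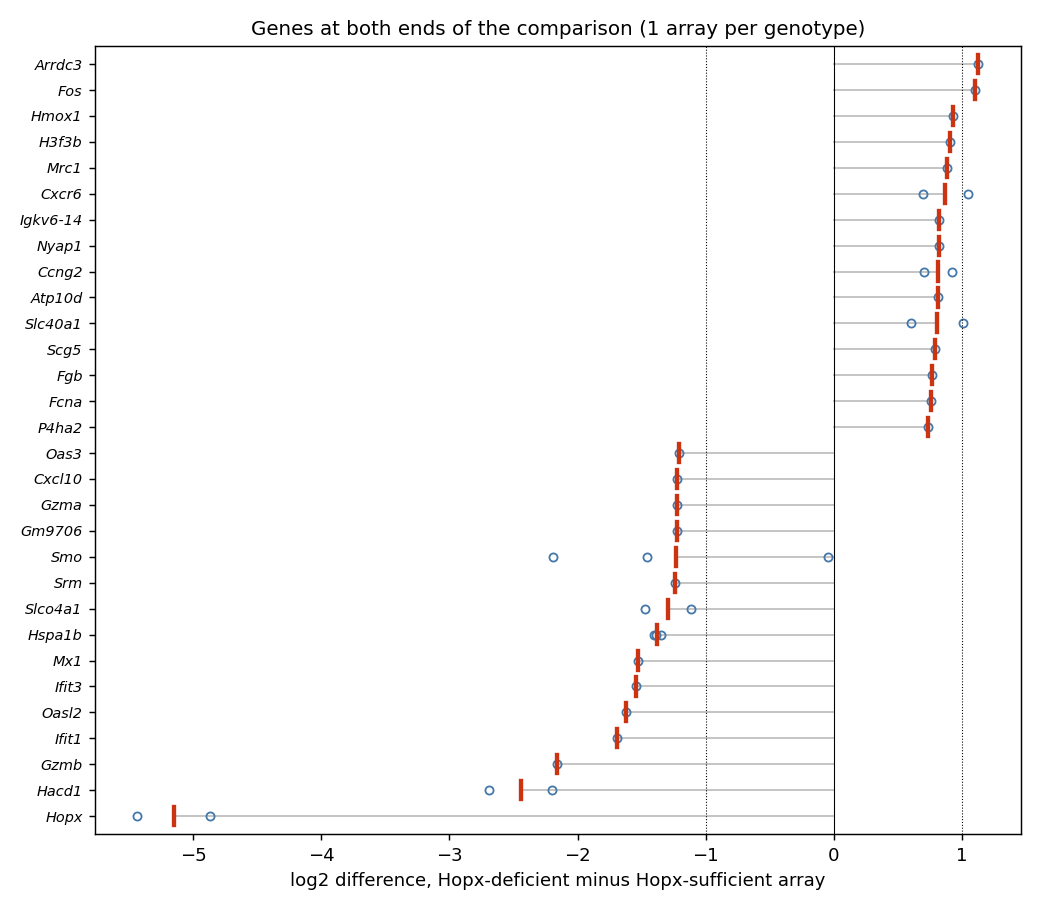
Log2 difference between the Hopx-deficient and the Hopx-sufficient array (x axis) for Hopx and the other genes at the 2 ends of the ranking (y axis), 15 at each end. Open circles are single probe sets, red bars the mean of a gene's probe sets, and dotted lines mark 2-fold; Hopx lies at -5.15, and on the higher side only Arrdc3 and Fos pass 2-fold.

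At the other end, Arrdc3, an arrestin-domain gene, was 2.19-fold higher and Fos, a subunit of the AP-1 transcription factor, was 2.15-fold higher, each measured by 1 probe set. The remaining genes of the 15 highest did not reach 2-fold. Several are known from tissue macrophages that handle iron and haem: the haem oxygenase gene Hmox1 was 1.90-fold, the mannose receptor gene Mrc1 1.85-fold, the iron exporter gene Slc40a1 1.75-fold and the ficolin gene Fcna 1.69-fold higher. The others were H3f3b, a replacement histone gene (1.87-fold), the chemokine receptor gene Cxcr6 (1.83-fold, probe sets at 0.70 and 1.05), the cyclin G2 gene Ccng2 (1.76-fold), Igkv6-14 (1.77-fold), Nyap1 (1.77-fold), Atp10d (1.76-fold), Scg5 (1.73-fold), Fgb (1.70-fold) and P4ha2 (1.66-fold). Igkv6-14 belongs to the immunoglobulin kappa variable family, whose members share sequence.

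Of 24 gene lists, 23 held enough measured genes to be placed among random lists. The medians of 5 lists lay below and of 7 lists above the central 95% of random lists, and 11 lay within it.

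The interferon response list lay furthest from 0: 26 of its 27 measured genes were lower in Hopx-deficient cells, 5 of them at least 2-fold and 11 at least 1.5-fold. Its median was -0.41, below all 10000 random lists. Beyond the Ifit, Oas and Mx genes, Rsad2, an antiviral enzyme gene, was just over 2-fold lower with 3 probe sets, Bst2 was 1.80-fold lower, and Irf7, the interferon-regulated transcription factor gene, was 1.64-fold lower. The highest member stood at 0.07. Of the DC and macrophage markers, a list that did not stand apart, the MHC class II genes Cd74, H2-Aa, H2-Ab1 and H2-Eb1 differed by -0.15 to -0.38 and their regulator Ciita by -0.09; these 5 were picked after their values were seen, and none reached 1.5-fold.

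Genes of cell division, chiefly those of DNA replication, and of biosynthesis were lower together. In the cell cycle list 33 of 39 measured genes were lower, 8 of them by at least 1.5-fold, none by 2-fold, and the median was -0.21, again below all random lists. Cdc6, which loads the replicative helicase, was 1.95-fold lower, the replication factor gene Gins2 1.85-fold and Ccne1, encoding cyclin E1, 1.78-fold. Of the 17 measured cholesterol synthesis genes 15 were lower (median -0.30), led by Idi1 (1.96-fold), Cyp51 (1.60-fold) and Sqle (1.56-fold). Of 14 glycolysis genes 11 were lower (median -0.29), with log2 differences of -0.86 for Hk2, a hexokinase gene, -0.57 for Tpi1 and -0.56 for Pkm. In the list of heat shock and dissociation stress genes, 11 of 12 were lower (median -0.30). After Hspa1b, the mitochondrial chaperone genes Hspd1 (1.63-fold) and Hspe1 (1.46-fold) differed most. The medians of these 3 lists also lay below all random lists. Ribosomal protein genes, by contrast, had a median of -0.01, within the random range. Their most different members were Rpl14 (-0.44), Rps20 (-0.19, with 4 probe sets between -0.58 and 0.07) and Rps16 (0.16).

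The AP-1 list was chosen in the knowledge that published work on these cells concerns AP-1, so its direction is not independent evidence. It did not stand apart as a group: 6 of 10 genes were higher and 4 lower, the median was 0.04, at percentile 73.7 of random lists, and only Fos reached 2-fold. Jun was 1.19-fold higher by its mean, but its probe sets gave 0.53 and -0.03. Fosl2 was 1.42-fold lower, with probe sets at -0.88 and -0.14. Other immediate-early genes, which signals induce within minutes, did stand apart. Of 25, 17 were higher, the median was 0.18, above all random lists, and 3 were at least 1.5-fold higher: the phosphatase genes Dusp6 (log2 difference 0.68) and Dusp1 (0.67) and the mRNA-decay gene Zfp36 (0.62).

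Genes typical of Tregs and of resting T cells were slightly higher in Hopx-deficient cells. Of 32 measured genes of the Treg signature 24 were higher, with a median of 0.14 (percentile 99.99), and Gzmb was the single member at least 2-fold apart. Nrp1, encoding neuropilin-1, was 1.45-fold higher with 4 probe sets between 0.48 and 0.61, and Gpr83 was 1.40-fold higher. In the naive and recirculation list 14 of 15 genes were higher (median 0.28), led by Klf2 (1.47-fold), a factor that drives expression of S1pr1 (1.46-fold), the receptor for exit from lymph nodes, and by the integrin gene Itga6 (1.36-fold). Anergy and inhibitory receptor genes were higher in 17 of 20 cases (median 0.24); apart from Nrp1, the ubiquitin ligase gene Rnf128 (1.34-fold) and Dgka (1.32-fold) differed most, and 6 of the 20 genes also belong to other lists. Without shared members the median of the anergy list was 0.12 (percentile 98.8) and that of the Treg signature 0.081 (percentile 97.8). TCR signalling genes were higher in 23 of 26 cases (median 0.18), among them Ptpn22 (1.40-fold), Cd28 (1.26-fold) and Prkcq (1.25-fold). The medians of the naive, anergy and TCR lists lay above all random lists. None of these 3 lists held a member 1.5-fold apart.

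Lineage factors of helper T cells had a median of 0.11 (percentile 99.3) over members that went both ways. Irf8 (-0.67) and Tbx21, encoding T-bet (-0.56), were lower, while Cxcr3 was higher (0.53). The TGF-beta list had a median of 0.10 (percentile 98.7), with Itgae at 0.39, Tgfbr1 at 0.26 and Tgfbr3 at -0.27. The probe sets of Tgfbr3 disagreed, at -0.60 and 0.06. When the most different probe set stood for each gene, the TGF-beta list fell to percentile 92.1.

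Cytokine genes did not stand apart (27 genes, median 0.06, percentile 92.6), and none was 1.5-fold different. The list did stand apart without members shared with other lists (0.10, percentile 98.1). It also did so without the probe sets with the finest steps (0.094, percentile 98.1). Ccl3 was 1.42-fold higher, Il2 1.32-fold lower and Fasl 1.30-fold lower. Apoptosis regulators (29 genes) had a median of 0.04, with the pro-apoptotic Bbc3 at 0.49, Bcl2 at 0.40 and Cycs at -0.42. The NF-kB list (17 genes) had a median of 0.03, with Map3k14 at 0.41, Nfkbiz at 0.30 and Rel at -0.24. Targets of serum response factor, a partner of Hopx in other tissues, had a median of -0.03 over 21 genes; Cnn3, a calponin gene, was 1.96-fold lower with all 6 probe sets between -1.18 and -0.78, and Fhl2 (-0.42) and Vcl (-0.28) followed.

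**Figure D2:**
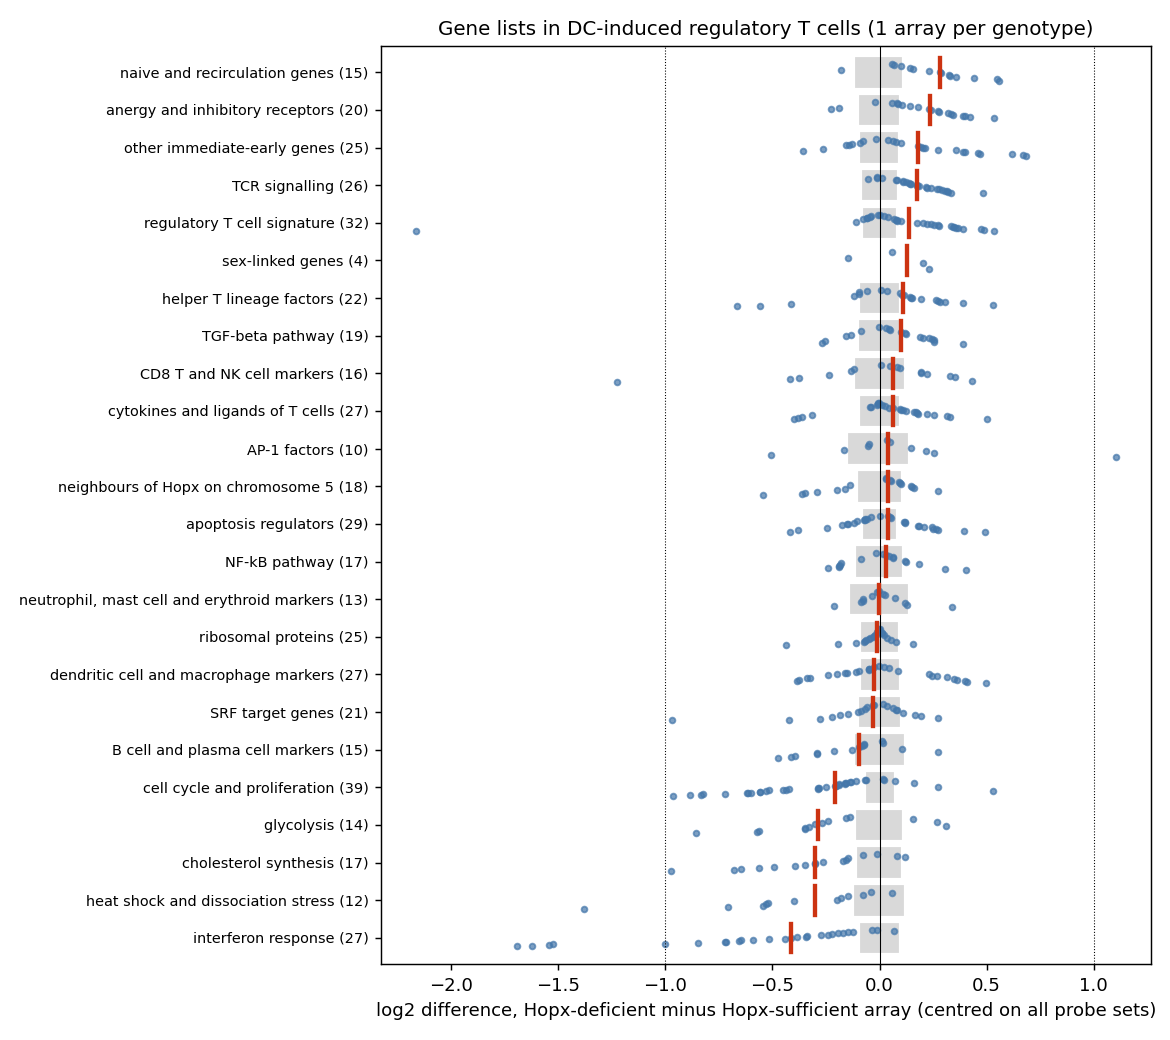
Log2 difference between the Hopx-deficient and the Hopx-sufficient array (x axis) for the members of 24 gene lists (y axis, number of measured genes in brackets). Points are genes, red bars list medians, grey boxes the central 95% of the medians of 10000 random lists, and dotted lines mark 2-fold; the interferon response median of -0.41 lies furthest below its box and the naive and recirculation median of 0.28 furthest above.

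None of the 4 lists of markers of other cells that had been fixed in advance stood apart. With the most different probe set standing for each gene, the B cell list (-0.22, percentile 0.65) and the CD8 T and NK cell list (0.15, percentile 98.0) did. A list of 16 tissue macrophage markers added after the data were seen stood apart as higher (median 0.26). DC and macrophage markers had a median of -0.02 over 27 genes, with 12 higher and 15 lower; Cd14 (0.50), C1qb (0.41) and C1qc (0.40) were the most different. B cell and plasma cell markers had a median of -0.09 (15 genes, percentile 4.53), with Fcmr at -0.48, Cd79a at -0.41 and Ebf1 at -0.40. CD8 T and NK cell markers had a median of 0.06 (16 genes), Gzma being their only member past 2-fold, with Nkg7 at 0.43 and Klrd1 at -0.42. Neutrophil, mast cell and erythroid markers had a median of -0.0031 (13 genes), with Mcpt4 at 0.34, Mpo at -0.21 and S100a8 at 0.13. The genes listed in advance as lying near Hopx had a median of 0.04 (18 genes), with Ppat at -0.54, Noa1 at -0.36 and Pdcl2 at -0.35. Median and mean differed in sign in 4 of these lists, the means being 0.02 for DC and macrophage markers, -0.03 for CD8 T and NK cell markers, 0.02 for the neutrophil list and -0.05 for the neighbours of Hopx. Among the 4 sex-linked genes measured, too few to be placed, Eif2s3y (0.23), Uty (0.20) and Kdm5d (-0.15) differed most.

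Control probe sets gave the size of purely technical differences. The 18 probe sets of hybridization spike-ins, which carry no mouse sequence, ranged from -0.22 to 0.01 with a median of -0.12. They differed by spike-in. Those of BioB lay between -0.22 and -0.16 and those of BioC between -0.17 and -0.10. Those of BioD lay between -0.077 and -0.0041 and those of Cre between -0.08 and 0.01. Whether this technical difference depends on signal was not tested. The deposited values hold no levels, and the value steps give at most a coarse bound on the signal. The 27 probe sets of bacterial poly-A RNA ranged from -0.17 to 0.78, with a median of 0.03. The 3' minus 5' difference, a sign of RNA integrity, was -0.09 for Gapdh, 0.00 for beta-actin, 0.19 for pyruvate carboxylase and 0.53 for the transferrin receptor. For 18S ribosomal RNA, which has no poly-A tail, it was -0.11, its 3' and 5' probe sets standing 0.34 and 0.45 higher on the Hopx-deficient array. The median of the spike-ins was thus about as far from 0 as the medians of the TGF-beta, lineage and Treg lists, but had the opposite sign. The cell cycle median (-0.21) had the sign of the spike-in median and lay within the spike-in range. Of the 39 cell cycle genes, 48.7% lay below the lowest spike-in probe set and 35.9% within the range. A technical shift of that size is therefore not excluded for the cell cycle list as a whole.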

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

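The tests on the interferon response genes were chosen after the differences were seen, including the use of tissue macrophage markers there; the test of those markers for the macrophage pattern was set before their values were read. A signal outside the comparisons lay in the probe sets that carry no or several gene symbols: of 10092, 7 were at least 2-fold lower and 3 at least 2-fold higher in Hopx-deficient cells. The lowest, 1439200_x_at, differed by -1.71 and the highest, 1427820_at, by 1.21. Their genes are unnamed here.

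The interferon response genes were lower, with a median of -0.41. A technical shift of spike-in size is argued against, since 70.4% of the 27 members lay below the lowest hybridization spike-in probe set. A uniform difference in hybridization gain is removed by the centring. A gain that depends on signal was not tested, since the deposited values hold no levels and the value steps give at most a coarse bound. Fewer tissue macrophages in the Hopx-deficient sort are argued against too, since their held-out markers were higher (median 0.26). Fewer cells with MHC class II remain open, because Cd74, H2-Aa, H2-Ab1 and H2-Eb1 had a median difference of -0.29, short of the interferon median; these 4 genes were picked after their values were seen. Exposure or handling of the animals cannot be told apart from genotype with 1 array of each, and a Hopx-linked difference is likewise untested.

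Genes known from tissue macrophages were among the most increased, with Hmox1 at 0.93, Mrc1 at 0.89, Slc40a1 at 0.80 and Fcna at 0.76. More macrophage RNA in the Hopx-deficient sort is a candidate explanation: 16 measured markers that had not been used to see the pattern had a median of 0.26, above all 10000 random lists. Cd5l (0.54), Apoe (0.48), Cd163 (0.47), Spic (0.37) and Vcam1 (0.34) were higher, while Marco (-0.05), Vsig4 (-0.07) and Msr1 (-0.11) were not. The list of DC and macrophage markers fixed in advance did not stand apart (median -0.02, 12 higher and 15 lower). Of its macrophage markers, picked after their values were seen, C1qa (0.36), Adgre1 (0.35) and Cd68 (0.31) were higher, but Lyz2 (-0.38) and Itgam (-0.16) were lower, and Mpeg1 (-0.05) and Tyrobp (0.02) were near 0, so not all macrophage transcripts rose. The gate on CD25 and Foxp3 is meant to exclude macrophages, but the purity of the sorts is not given in the sources used here. A change of these genes within T cells was not tested.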

How the results depend on the processing

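No paired analysis was possible because each genotype has 1 array, and no array could be left out. Of the settings chosen before the data were examined, intensity-dependent centring, quantile normalization, the filters on dim probe sets, the second brightest probe set and the floors and pseudocounts were not run, since the table holds centred log values and no levels; for the same reason it stays largely unknown which small differences sit near background. All alternatives other than no centring and the thresholds were chosen after seeing the data. The counts of 2 higher and 26 lower genes became 54 and 238 at 1.5-fold, and 0 and 5 at 3-fold. They became 22 and 108 if the values were natural logs, and 5 and 43 when the most different probe set stood for each gene. In the last case 28 of the 28 genes were still included. That was fixed in advance, since the most different probe set lies at least as far from 0 as the mean. The counts moved by less than 1.5 times under the other 5 settings tried. Without probe sets that can cross-hybridise 25 of the 28 genes remained, and Smo came to -0.75. The side of the random range was kept by all 23 placed lists with the median probe set, without cross-hybridising probe sets and with random lists matched on size alone. Leaving out the centring moves list medians and random medians alike, so it could not change the side and is no check of it. With the most different probe set, the TGF-beta list (0.16) was no longer apart, and the B cell (-0.22) and CD8 T and NK cell (0.15) lists came to stand apart. The cytokine list came to stand apart without the probe sets with the finest steps (0.094) and without members shared with other lists (0.10). Without shared members the anergy (0.12) and Treg (0.081) medians were over 1.5 times smaller, though still apart. With the most different probe set the heat shock (-0.55), cell cycle (-0.37) and lineage (0.17) medians were over 1.5 times larger. No list median that stood apart and no gene past 2-fold reversed.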

Other observations

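Ribosome biogenesis and the supply of building blocks were lower on the Hopx-deficient array, as were other biosynthesis genes. The groups in this paragraph were chosen after the data had been seen, but before the values of their members were read. All 28 measured ribosome biogenesis genes were lower, 8 of them at least 1.5-fold, with Rrp12 at 1.95-fold, Nop2 at 1.71-fold and Nolc1 at 1.62-fold. Of these 28 genes, 96.4% lay below the lowest hybridization spike-in probe set. That argues against a technical shift of spike-in size for this list, while a gain that depends on signal was not tested. The list of nucleotide, serine and amino acid supply also holds Odc1 (-0.34) and the transferrin receptor gene Tfrc (-0.55). All 14 of its measured genes were lower (median -0.51), led by the one-carbon enzymes Shmt2 (1.83-fold), Mthfd1 (1.68-fold) and Shmt1 (1.65-fold). Myc, a driver of such genes, differed by -0.09 on 1 probe set. Oxidative phosphorylation genes were lower in 23 of 26 cases but by little (median -0.11, percentile 0.63), no further from 0 than the hybridization spike-ins (median -0.12), so a technical shift of that size is not excluded. Genes of antigen processing for MHC class I, many of them inducible by interferon, were not shifted (12 genes, median -0.03).

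Within the cell cycle list, the split of which was chosen after its values were seen, all 18 genes of DNA replication and its control were lower (median -0.56), and the 21 other genes, mostly of mitosis, had a median of -0.14 with 6 higher. The second part also lay low among random lists (percentile 0.27), but its median was about the size of that of the spike-ins: Cdk1 differed by -0.52, Bub1b by -0.29 and Aurkb by -0.28, against -0.07 for Mki67 and 0.53 for Ccnb2. In the opposite direction, all 17 genes of a list linked to FOXO factors and quiescence were higher, among them Pik3ip1 (1.53-fold), Btg1 (1.51-fold) and Sesn1 (1.37-fold).

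A hypothesis is that the Hopx-deficient cells on this array were in a slower growing state. The ribosome biogenesis median (-0.43) lay below all random lists and the FOXO-linked median (0.38) above all of them, as the hypothesis predicts. Both tests were set before the values of their members were read. Both lists were, however, added after other growth genes had been seen to be lower on the same 2 arrays, so they are not independent support. The tests of T cell share and RNA integrity were chosen afterwards. Whether the cells also differed in activation stays open, because activation-linked genes went both ways: immediate-early genes were higher (median 0.18, above all random lists), but Nr4a1, Nr4a2 and Nr4a3 among them stood at -0.08, -0.13 and -0.16, Gzmb (-2.16), Tbx21 (-0.56) and Irf4 (-0.41) were lower, and the naive and recirculation list was higher (median 0.28). A lower share of T cells in that sort is argued against by TCR signalling genes, whose median was 0.18. This holds only if the level of these genes per T cell was unchanged, which was not tested. Lower RNA integrity stays open, since 2 of the 4 polyadenylated mouse control transcripts had a 3' minus 5' difference at or below 0.1 and the other 2 did not (18S ribosomal RNA, at -0.11, was not counted, as it is not polyadenylated). With 1 array per genotype, Hopx cannot be told apart from the time since activation or the handling of either sort.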
